A study of Danio rerio with 18 samples.

How the data were processed

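RNA was sequenced from pooled zebrafish embryos at 24 hours post fertilization (hpf), all positive for a transgene, in 18 libraries that form 6 groups of 3. AngioTag and RiboTag are transgenic lines whose ribosomes carry an HA tag, and an HA antibody pulled the tagged ribosomes with their bound RNA out of a lysate (translating ribosome affinity purification). The AngioTag IP and RiboTag IP groups are this immunoprecipitated RNA, and AngioTag input and RiboTag input are the RNA of the whole embryos of the same lines. The FACS sorted group is RNA of GFP-positive endothelial cells isolated by fluorescence-activated cell sorting, and FACS total is its whole-embryo counterpart, both from AngioTag transgenic embryos per the labels. That the tagged ribosomal protein is rpl10a and that kdrl drives the endothelial line was taken from knowledge of the study, not from the labels.

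The authors deposited a single table of raw counts per Ensembl gene, with 1 column per library and no normalization. The labels name STAR 2.4.2a, RSEM 1.2.22, DESeq2 without a version and genome build GRCz10, without the role of each. The values are whole numbers, and whether they are gene counts or rounded RSEM estimates is not stated, nor are the annotation release and the use of strand. Libraries were made with a stranded mRNA kit after poly(A) selection or ribosomal RNA depletion of 500 ng RNA, and the labels do not say which library had which. Reads shared by near-identical paralogs (globin, histone, myosin and actin copies) can be split between them by RSEM, so values of single copies are less certain. Nothing states that the 3 samples of a group were separate pools of embryos, and p-values measure the spread between these samples.

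The table held 25193 genes, of which 22548 (89.5%) were given a symbol from an Ensembl name table, and 3343 shared a symbol with another gene. Every column and every library was used. Library totals ran from 18.3 to 49.5 M (mega) counts. For pairs of samples of a group, the chi-square per degree of freedom against counting error ran from 17.4 to 534.9 over genes with at least 20 counts. The table of gene classes supplied with the reference carried no Ensembl identifiers and belonged to another genome build, so the comparison of transcript classes that had been planned was not run.

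Genes were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 on the groups compared alone. Low counts were removed with filterByExpr by group (minimum count 10, minimum total count 15), TMM factors scaled the libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 8 comparisons were each IP against its input, sorted cells against FACS total, AngioTag IP against RiboTag IP, both pairs of whole-embryo references, and 2 differences of enrichments (AngioTag minus RiboTag, AngioTag minus FACS) as interaction contrasts over 12 libraries. Fold changes are log2 values with a standard error. This is the absolute log2 fold change divided by the square root of its F statistic, so a distance in standard errors restates that test. Levels are normalized CPM, scaled with TMM factors over all 18 libraries and 20517 genes, as mean ± SD (n = 3).

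A total of 29 gene lists were counted in every comparison, with the p-values adjusted over all genes tested and adjusted over the list alone. Lists with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 28 lists tested in a comparison, again with an estimated correlation, and with fry. Of 721 list entries, 641 matched the table, through the symbols given or their aliases, giving 631 genes. Lists share members: 8 of the venous and lymphatic and 4 of the VEGF genes are also in the endothelial list, and 6 arterial genes are in the Notch list. Fold changes were also correlated across genes for 2 pairs of enrichments.

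The gene lists, the tests, the alternatives and the rule for genes named were set before the data were examined. The rule takes rpl10a and kdrl, the 10 genes with the largest rise and the 6 with the largest fall in each comparison (5 and 5 between whole-embryo references) that passed the threshold with an average log2 CPM of at least 2, a standard gene symbol and no overlap of the groups' libraries, and up to 4 members per list in the main direction and 2 in the other, or the 2 members with the highest CPM where none passed. The rule asked for lower-case symbols, but the name table writes many symbols in capitals, so capitals were accepted. Among the genes under the rule, those whose call held with any 1 library left out were preferred as examples, a preference set after the values were seen. Members named to complete short groups were also chosen after their values were seen.

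Alternatives were median-of-ratios (RLE) and upper-quartile scaling, DESeq2 1.42.0, no low-count filter and a stricter one of 1 CPM, all 18 libraries in 1 fit, mitochondrially encoded and histone genes left out, same-numbered samples as a block, an absolute log2 fold change of at least 1, and each library left out in turn. Same-numbered samples were taken as paired where deviations from the group means correlated above 0.1 in all 3 pairs. They did so for AngioTag IP and input (r = 0.26, 0.12 and 0.16) and for RiboTag IP and input (0.13, 0.47 and 0.32), but not for FACS sorted and total (0.29, 0.02 and 0.15), across genes. The AngioTag IP and RiboTag IP samples correlated at 0.10, 0.12 and 0.11, just past that limit. Alternatives chosen after seeing the data left out zgc:158463, left out 3 doubted libraries together (AngioTag IP 1, FACS sorted 2 and RiboTag IP 2), and took AngioTag input as the reference for sorted cells.

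The procedure was tested on simulated data with the spread of each comparison. With 100 genes changed 4-fold, the test recovered 88% for AngioTag IP against input, 62% for RiboTag, 46% for FACS, 40% and 19% for the AngioTag minus RiboTag and AngioTag minus FACS contrasts, 67% for AngioTag IP against RiboTag IP, 95% for the inputs and 88% for FACS total against AngioTag input. For a 2-fold change, given to another 100 genes, these values were 24%, 6%, 0%, 1%, 0%, 15%, 67% and 17%. In the data far more genes were called in most comparisons, up to 46.3% of those tested. The Benjamini-Hochberg cutoff loosens as more genes change, so recovery in the data can be higher than in these simulations.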

Results

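RNA from whole zebrafish embryos at 24 hpf, RNA bound to tagged ribosomes and RNA of sorted endothelial cells was counted per gene in 18 libraries, 3 in each of 6 groups. Library totals for samples 1 to 3 were, in M counts, 20.7, 42.1 and 39.8 in the AngioTag IP, 33.6, 43.4 and 40.7 in AngioTag input, 29.5, 35.2 and 32.1 in the RiboTag IP, 36.4, 49.5 and 35.3 in RiboTag input, 41.3, 18.3 and 38.4 in FACS sorted, and 42.0, 40.8 and 45.5 in FACS total. Mitochondrially encoded genes held 0.273% ± 0.0208 (SD, n = 3) of counts in the AngioTag IP and 0.14% ± 0.0265 in the RiboTag IP, against 4.19% ± 0.392 and 4.2% ± 0.161 in their inputs, 2.37% ± 0.401 in FACS sorted and 2.76% ± 0.632 in FACS total. The gene zgc:158463 took 15.27% of FACS sorted 2 and 4.19% of AngioTag IP 1, but 0.01% to 1.11% of the other libraries. Cytosolic ribosomal protein genes held 7.33% of RiboTag IP 2 and 14.88% and 16.88% of the other RiboTag IP libraries.

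**Figure D1:**
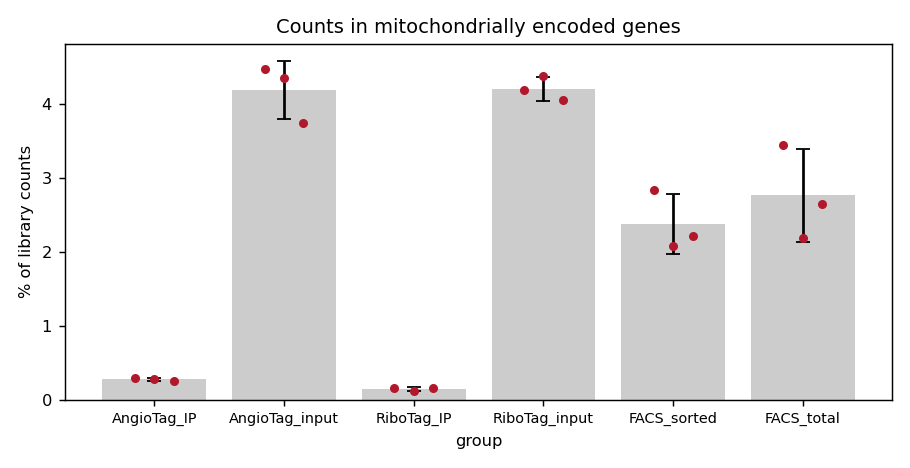
Share of each library's counts in mitochondrially encoded genes (y axis, % of library counts) for the 6 groups (x axis), with bars for means, error bars for SD (n = 3) and points for libraries. Both IP groups lie below 0.3%, and the other 4 groups average 2.37% to 4.2%.

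AngioTag IP against AngioTag input asks which messages are held by the ribosomes tagged in the endothelium. Endothelial genes rose in the IP: 50 of 56 tested passed the test upward and 1 downward, the same numbers when adjusted over the list alone, with a median log2 fold change of 3.80. The VEGF receptor gene kdrl (ENSDARG00000105215) averaged 506 ± 171 CPM in the IP and 26.9 ± 3.26 in the input (SD, n = 3), a log2 fold change of 4.22 ± 0.28 (SE, adjusted p = 3.45e-05), with all 3 IP libraries above all 3 inputs. Among the largest rises were clec14a (5.77 ± 0.28) and pecam1 (5.29 ± 0.30), which encode endothelial surface proteins, and hhex (4.97 ± 0.29), a transcription factor of blood and endothelial progenitors. Camera found the list up (adjusted p = 2.48e-103, and 0.0691 with an estimated correlation). The single fall was in unc5b (-1.67 ± 0.34), whose adjusted p was 0.0615 without AngioTag input 3 and 0.0597 with all 18 libraries in 1 fit.

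Genes of venous and lymphatic endothelium rose in 10 of 13 cases (11 adjusted over the list alone), led by gpr182 (4.72 ± 0.30) and the scavenger receptor genes stab1 (4.31 ± 0.27) and mrc1a (4.05 ± 0.27). Camera gave the list an adjusted p of 2.49e-24, or 0.0833 with an estimated correlation. VEGF ligands and receptors rose in 9 of 13 cases (9 over the list alone), with flt1 at 4.41 ± 0.25, flt4 at 3.49 ± 0.22 and its ligand vegfc at 3.21 ± 0.24 (adjusted p = 2.38e-15, and 0.0429 with an estimated correlation). Of 8 arterial genes, 5 rose and 2 fell (5 and 2 over the list alone). The risers included sox17 (4.80 ± 0.54) and the Notch ligand and target genes dll4 (2.95 ± 0.20) and hey2 (2.94 ± 0.26), with jag2b and dlc. The fallers were unc5b and notch3 (-1.81 ± 0.38), the latter with an adjusted p of 0.0594 without AngioTag IP 3 and 0.0507 with all 18 libraries in 1 fit. The arterial list had an adjusted p of 8.17e-05, and 0.194 with an estimated correlation. Blood progenitor genes rose in 6 of 8 cases (7 over the list alone), including gfi1aa (4.97 ± 0.39) and lmo2 (2.56 ± 0.27), and myeloid genes in 16 of 21 (17), including lysozyme, lyz (5.03 ± 0.58), and the granule proteoglycan gene srgn (4.60 ± 0.54). Their camera p-values were 8.53e-08 and 2e-12, or 0.194 and 0.221 with an estimated correlation.

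All 12 mitochondrially encoded genes tested fell (12 adjusted over the list alone), by a median of -3.85 on the log2 scale (camera adjusted p = 1.13e-51, and 0.0429 with an estimated correlation). For mt-nd5 the level was 39.0 ± 17.3 CPM in the IP and 1372 ± 275 in the input. Of 29 skeletal muscle genes, 17 fell and 4 rose (19 and 5 over the list alone). The regulators of muscle formation mymk (-2.05 ± 0.38), myf5 (-1.83 ± 0.30) and myog (-1.61 ± 0.31) were among the falls. The rises were myosin heavy chain genes, myhz1.1 (1.33 ± 0.32), myhz1.2 (1.27 ± 0.30), myhz1.3 (1.07 ± 0.20) and smyhc1 (0.79 ± 0.24), the last 2 named after their values were seen, and without AngioTag IP 3 a single one passed. The call of smyhc1 was also lost without IP 1 or any 1 input (adjusted p of 0.0543 to 0.153) and with the stricter filter (0.054). Camera found the muscle list down at 2.36e-05, but 0.221 with an estimated correlation.

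Pigment and neural crest genes fell in 10 of 13 cases (11 adjusted over the list alone), including the tyrosinase gene tyr (-2.49 ± 0.35), in 5 without AngioTag IP 3 or input 3 and in 6 without input 2. Neural genes fell in 15 of 33 cases and rose in 1 (19 and 2 over the list alone). The riser, isl1 (0.71), lost its call without IP 3 or any 1 input (adjusted p of 0.0746 to 0.102). The number of falling neural genes was 26 without AngioTag IP 2, 7 without input 1 or 2 and 5 without IP 3 or input 3. Yolk and liver genes fell in 9 of 15 cases (12), including the apolipoprotein genes apoa4b.1 (-1.55 ± 0.25) and apoa1b (-1.33 ± 0.20), in 5 without input 2 or 3, and the protease gene ctsla rose (1.17 ± 0.23). Epidermal genes fell in 10 of 25 cases, including the claudin gene cldne (-1.29 ± 0.19), and 2 rose (11 and 2), the keratin genes keratin18 (1.92 ± 0.23) and krt8. That count of 10 became 16 without IP 1, 3 without IP 3, and 6, 4 and 5 without inputs 1, 2 and 3. Notochord and cartilage genes fell in 4 of 9 cases (8), with col8a1a at -3.19 ± 0.42 and col9a2 at -1.14 ± 0.17 beside tbxta and col11a2, in 7 without IP 1 and in 2 without IP 3 or any 1 input. Lens genes fell in 3 of 13 cases (4), with crybb1 at -1.37 ± 0.21 beside crybb1l1 and cryba4, in 5 without IP 2 and in 9 (11) with same-numbered samples as a block. With that block 12 pigment (12), 22 neural (25), 11 yolk and liver (13), 12 epidermal (13) and 6 notochord genes (8) fell. In the same fit 1 neural, 1 yolk and liver and 2 epidermal genes rose. Camera adjusted p-values in the order of this paragraph were 5.42e-06, 3.36e-05, 9.73e-05, 0.0197, 0.00146 and 0.00422, and 0.194, 0.427, 0.199, 0.221, 0.221 and 0.574 with an estimated correlation.

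Immediate early genes rose in 8 of 35 cases (8 adjusted over the list alone), with the transcription factor jund at 2.42 ± 0.36 and the kinase sgk1 at 1.63 ± 0.26, and in 13 without AngioTag IP 1. Basement membrane genes went both ways, 7 up and 4 down of 21 (7 and 5), with the collagen and laminin genes col4a1 (3.25 ± 0.27) and lama4 (2.80 ± 0.26) up and lamb2 (-1.64 ± 0.20), NID1 (ENSDARG00000068710), lama1 and col4a6 down, the last 2 named after their values were seen. The 4 falls became 7 without IP 1 and 2 without IP 3, input 1 or input 3, and the list's median was -0.04 against a mean of 0.38. Of 5 flow responsive genes, edn1 (2.48 ± 0.49) and klf2a (2.28 ± 0.33) rose and piezo1 (-1.34) fell (2 and 1), the last not without IP 2 or any 1 input (adjusted p of 0.056 to 0.159), with a median of -0.36 and a mean of 0.53. Notch genes rose in 4 of 19 cases, dll4, hey2, jag2b and dlc, and fell in 2, notch3 and dlb (-0.73) (4 and 3). The rises became 7 without IP 1, and the falls 0 without IP 3 and 1 without any 1 input. Mural genes rose and fell in 2 of 10 cases each (3 and 3), with foxc1a (1.97 ± 0.20) and tagln up and notch3 and tbx18 down, and the falls became 0 without IP 3 and 1 without any 1 input. Heat shock genes fell in 4 of 14 cases, including the chaperone partner bag3 (-1.25 ± 0.18) with hsp90aa1.1, hsp70.3 and hspd1, and hspa5 rose (0.82) (5 and 1). They fell in 2 without input 1 or 3, and the rise was lost without IP 3 or any 1 input (adjusted p of 0.0846 to 0.17). Camera adjusted p-values were 0.0106, 0.0978, 0.464, 0.0448, 0.679 and 0.0729 in this order. The calls for the immediate early and Notch lists were lost with an estimated correlation (adjusted p = 0.513 and 0.227), and the Notch list had 0.114 with same-numbered samples as a block.

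Cell cycle genes fell in 4 of 28 cases (4 adjusted over the list alone), led by the checkpoint gene bub1bb (-2.28 ± 0.24) with bub1, cenpf and mcm3, and in 2 without AngioTag input 3. Erythroid genes rose in 4 of 18 cases (4), including blf (1.76 ± 0.32, adjusted p = 0.0759 with all 18 libraries in 1 fit), and the globin genes hbbe3, hbae5 and hbae3, in 7 without IP 2 and in 1 without IP 3, input 2 or input 3. In the cardiac list myh6 (1.14 ± 0.16) and hand2 (0.72) rose and myl7 (-0.78) and both cmlc1 copies fell, of 9 tested (2 and 3). A single cardiac gene rose without IP 2, IP 3 or any 1 input, and none fell without IP 3, input 2 or input 3. The pronephros gene atp1a1a.5 (-1.61) fell alone among 7 (2), with 2 falling without IP 1 or IP 2 and 0 without IP 3 or any 1 input. Hatching gland genes he1a (-1.13) and he1b (-1.21) fell and cap1 (0.65) rose, of 4 (3 and 1), and no call was left without IP 3 or any 1 input. Histone genes rose in 4 of 16 cases (4), h2ax2, h2ax, h2az2 and h3f3b.1, and mitochondrial ribosomal protein genes in 4 of 73 (0), mrpl53, mrps26, mrpl52 and mrpl32. With same-numbered samples as a block the adjusted p was 0.068 for h2ax2 and 0.0567 for mrpl32. Without IP 2 these were 8 and 28, without input 2 they were 1 and 1, and without IP 3, input 1 or input 3 both were 0. Of 26 translation factor genes eif4ba rose (0.77, 0 over the list alone), but not without IP 3 or any 1 input (adjusted p of 0.0788 to 0.112), and without IP 2 a further rise and 2 falls passed. Among 81 cytosolic ribosomal protein genes, rpl10a (ENSDARG00000042905), the tagged protein, rose from 3081 ± 447 to 6957 ± 1181 CPM (1.16 ± 0.20, adjusted p = 0.00425) and rplp0 fell (-1.02) (1 and 0), the latter not without IP 3 or any 1 input (adjusted p of 0.078 to 0.143). The rises there were 4 without IP 1 and 3 without IP 2 or with the block, by which 2 pronephros genes fell. Camera gave 0.436, 0.0929, 0.727 and 0.181 for the first 4 lists and 0.573 and 0.109 for the last 2, while histone (0.0314) and mitochondrial ribosomal protein genes (0.0107) lost their calls with an estimated correlation (adjusted p = 0.574 and 0.767).

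Over all genes, 2170 rose and 2130 fell of 17913 tested, and 2352 and 2552 with same-numbered samples as a block. Upper-quartile scaling moved the median of all genes by -0.205 and gave 1461 and 3078. The counts were 1243 and 871 without AngioTag IP 3, 1126 and 947 without input 1, 1217 and 1223 without input 2, 1026 and 695 without input 3, and 3424 fell without IP 1. With all 18 libraries in 1 fit the calls of myhz1.1 (adjusted p = 0.0511), myhz1.3 (0.0695), smyhc1 (0.207), rplp0 (0.0578), atp1a1a.5 (0.0765), dlb (0.0917), piezo1 (0.117), isl1 (0.125), he1b (0.132), hspa5 (0.14), cap1 (0.169), he1a (0.173), hand2 (0.193) and myl7 (0.285) were lost. So were those of mrps26 (0.0542), cenpf (0.0553), cryba4 (0.057), hbbe3 (0.0973), mrpl53 (0.106), h2ax (0.114), hsp90aa1.1 (0.139), mrpl32 (0.14), hbae3 (0.144), mrpl52 (0.146), h2ax2 (0.151), hbae5 (0.162), col11a2 (0.225), hspd1 (0.254), hsp70.3 (0.305) and the cmlc1 copies (0.102 and 0.381). With upper-quartile scaling those of isl1 (0.0554), eif4ba (0.0586), cap1 (0.0744), hspa5 (0.0968) and hand2 (0.108) were, with those of hbae3 (0.0525), hbae5 (0.0549), mrpl53 (0.0598), h3f3b.1 (0.0801), mrpl52 (0.0849), h2ax (0.0851), h2az2 (0.0947), mrpl32 (0.122) and smyhc1 (0.128). The call of mrpl32 also ended with median-of-ratios scaling (0.0502), the stricter filter (0.0534) and same-numbered samples as a block (0.0567).

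**Figure D2:**
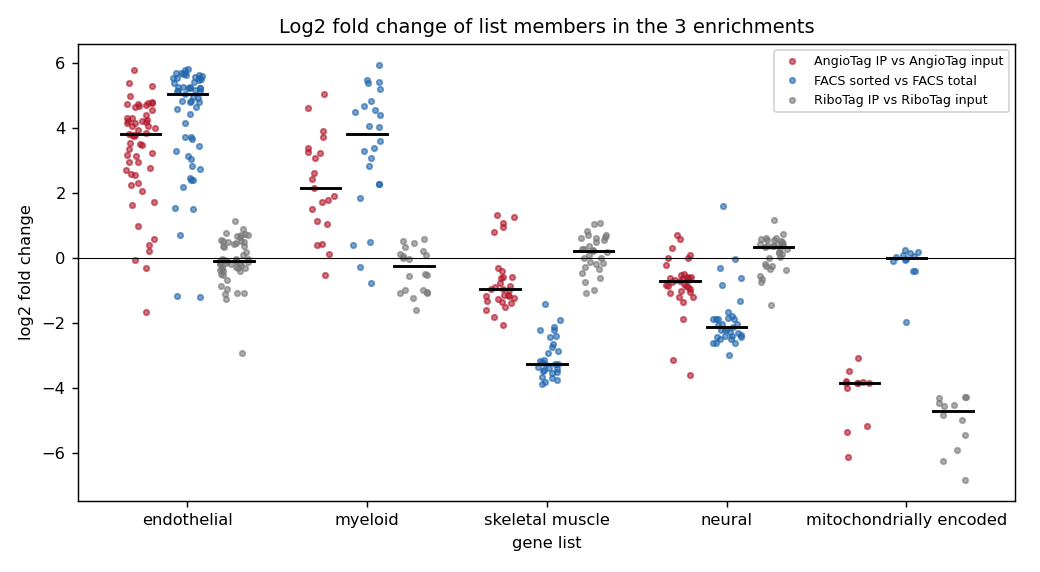
Log2 fold change (y axis) of the members of 5 gene lists (x axis) in AngioTag IP against input, RiboTag IP against input and FACS sorted against total, with a point per gene and a black line at the median. The endothelial median is 3.80 in AngioTag, -0.09 in RiboTag and 5.04 in FACS.

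RiboTag IP against RiboTag input compares ribosome-bound with total RNA across the whole embryo. Mitochondrially encoded genes fell in 11 of 12 cases (12 adjusted over the list alone), by a median of -4.70, with mt-nd5 at 21.0 ± 6.05 CPM in the IP and 1305 ± 337 in the input (-5.91 ± 0.35, adjusted p = 0.000616), and in 5 cases without RiboTag IP 1. Camera gave this list 1.66e-85, and 0.0113 with an estimated correlation. Yolk and liver genes fell in 4 of 15 cases (12 over the list alone), the lipoprotein genes apobb.1 (-2.65 ± 0.37), apoa4b.1 (-2.32 ± 0.30) and mtp (-2.15 ± 0.30) and the transferrin gene tfa (adjusted p = 0.0734 with all 18 libraries in 1 fit). The count was 0 without IP 1 or any 1 input, 9 without IP 2, 10 without IP 3, 10 by DESeq2 and 14 with same-numbered samples as a block, and camera's adjusted p was 4.87e-16, or 0.734 with an estimated correlation. Several genes of RNA binding and splicing proteins were among the largest rises, wbp11 (1.98 ± 0.20), hnrnpa1a (1.97 ± 0.24), acin1a (1.80 ± 0.25) and ewsr1b (1.76 ± 0.24). These 4 calls were lost without IP 1 (adjusted p of 0.0754 to 0.123) or without any 1 of the inputs (0.0721 to 0.23). The replication gene mcm7 rose (1.67 ± 0.21) as the single cell cycle gene of 28, with 11 up and 1 down adjusted over the list alone, 0 up without IP 1 or any 1 input and 7 up without IP 2. With the block 9 cell cycle genes rose and 2 fell (15 and 2). Camera found this list up at 8.91e-06, but 0.781 with an estimated correlation.

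Endothelial genes gave no call in RiboTag by edgeR without a block, 0 of 53 in either direction, with 9 up and 2 down at an unadjusted p below 0.05, 1 and 1 adjusted over the list alone, and 1 and 1 by DESeq2. Their median was -0.09, and without RiboTag IP 2 the numbers were 2 and 4, and without RiboTag IP 3 they were 0 and 1. These same-numbered samples were paired by their correlations, and with them as a block 5 endothelial genes rose and 2 fell (5 and 3). The value for kdrl was -0.18 ± 0.25 (adjusted p = 0.743) and for rpl10a -0.05 ± 0.38 (adjusted p = 0.958). Neural genes gave 0 of 33 calls by edgeR, with 6 up and 0 down at an unadjusted p below 0.05, 2 and 0 by DESeq2 and 1 and 0 adjusted over the list alone. Camera gave 0.0268, or 0.781 with an estimated correlation and 0.0584 with the block. Without RiboTag IP 2 or IP 3, 1 and 2 neural genes rose, and with the block 4 rose and 2 fell (5 and 3). In total 127 genes rose and 90 fell of 18134 tested, 3362 having an unadjusted p below 0.05. With same-numbered samples as a block 1306 rose and 1268 fell, and DESeq2 called 800 and 649. The numbers were 0 and 5 without IP 1, 864 and 1014 without IP 2, 408 and 214 without IP 3, and 0 and 10, 1 and 14, and 1 and 10 without inputs 1, 2 and 3.

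FACS sorted against FACS total compares cells sorted as GFP-positive endothelium with their reference, and genes of blood cells also rose in them. Endothelial genes rose in 54 of 57 cases and 1 fell (54 and 2 adjusted over the list alone), with a median of 5.04. The list had a camera adjusted p of 4.21e-87, or 0.036 with an estimated correlation. The levels of kdrl were 1131 ± 229 CPM in sorted cells and 32.4 ± 4.21 in FACS total (5.14 ± 0.31, adjusted p = 3.82e-05). Other rises were flt1 (5.82 ± 0.52), kdr (5.69 ± 0.35), the transcription factor sox18 (5.69 ± 0.48) and the gap junction gene gja4 (6.13 ± 0.65). The fall was in nr2f2 (-1.21 ± 0.27), a transcription factor of veins that many other tissues express, with an adjusted p of 0.0541 without FACS sorted 1, and 2 endothelial genes fell without FACS total 3. Venous and lymphatic genes rose in 12 of 13 cases and nr2f2 fell (12 and 1), with stab1 at 5.78 ± 0.31 and stab2 at 5.40 ± 0.32. Myeloid genes rose in 19 of 24 (19), with lyz at 5.94 ± 0.75 and srgn at 5.48 ± 0.44, and both lists held with an estimated correlation (adjusted p = 0.036 and 0.036). VEGF genes rose in 9 of 13 cases and 1 fell (9 and 1), the ligand gene VEGFA (ENSDARG00000034700, -2.07 ± 0.29), with 2 falling without FACS sorted 2. Blood progenitor genes rose in 7 of 9 (7), with gata2a at 3.44 ± 0.34, arterial genes in 6 of 9 (7), with dll4 at 5.50 ± 0.58, and flow responsive genes in 4 of 6 (4), with klf2a at 3.82 ± 0.31 beside klf2b, piezo1 and edn1. Camera found these last 4 lists up at 9.1e-10, 4.58e-05, 3.19e-05 and 0.000578, but 0.0933, 0.077, 0.166 and 0.166 with an estimated correlation.

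Several lists of other tissues fell in sorted cells. All 29 skeletal muscle genes did (29 adjusted over the list alone), including cav3 (-3.88 ± 0.71) and tpma (-3.68 ± 0.60), and 27 of 33 neural genes (29), including ascl1b (-2.99 ± 0.44) and sox19a (-2.61 ± 0.30). Lens genes fell in 10 of 14 cases (11), with lim2.1 at -2.12 ± 0.45. Epidermal genes fell in 16 of 25 cases, with anxa1b at -4.07 ± 0.70, and keratin18 (1.92 ± 0.36) and krt8 rose (16 and 2). They fell in 9 without FACS sorted 1 and in 10 with same-numbered samples as a block, and a single one rose without FACS sorted 1 or 2 or FACS total 1 or 2. Camera adjusted p-values were 4.07e-16, 1.97e-14, 3.19e-05 and 1.82e-05, or 0.338, 0.234, 0.159 and 0.534 with an estimated correlation. Fewer members fell in other lists, 4 of 13 pigment (4), 4 of 9 notochord (8), 4 of 7 pronephros (5, and 1 up), 3 of 10 cardiac (4) and 2 of 12 yolk and liver genes (2), with 1 up (1) in each of the last 2. Camera gave them 0.0123, 0.00459, 0.0431, 0.129 and 0.128, or 0.565, 0.534, 0.352, 0.648 and 0.651 with an estimated correlation. Pigment falls were 11 without FACS sorted 3. Notochord falls were 8 without FACS sorted 2, 1 without sorted 1 or 3 and 2 without any 1 total. Cardiac falls were 2 without FACS sorted 2 or 3 or total 2 or 3 and 1 without total 1, and the rise was lost without sorted 1 or total 2. Yolk falls were 0 without FACS sorted 1, 4 without sorted 3 or with the block and 1 without total 1 or 3. Erythroid genes rose in 6 of 18 cases (17 over the list alone), with a median of 2.26. This count was 15 without FACS sorted 2, 0 without FACS sorted 3, total 1 or total 2, 2 without total 3, and 12 by DESeq2, and the camera p of 0.00459 was 0.661 with an estimated correlation. Mitochondrially encoded genes gave 0 of 12 calls by edgeR and 0 adjusted over the list alone, with 0 up and 1 down at an unadjusted p below 0.05 and 0 and 1 by DESeq2, and mt-co1 at 0.24 ± 0.29 (adjusted p = 0.598). In total 2678 genes rose and 2868 fell of 19326 tested. Upper-quartile scaling moved the median by -0.205 and gave 2199 and 3657. With single libraries left out, 1563 fell without FACS sorted 1, 1668 and 1653 passed without FACS total 1, and 1821 fell without FACS total 2.

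The difference between the AngioTag and RiboTag enrichments asks what the endothelial pull-down holds beyond an immunoprecipitation from the whole embryo. Endothelial genes were higher in the AngioTag enrichment in 47 of 56 cases and lower in 0 (50 and 1 adjusted over the list alone), with a median difference of 3.86. Examples were clec14a (5.39 ± 0.47) and pecam1 (5.33 ± 0.43), and kdrl differed by 4.38 ± 0.38 (adjusted p = 1.09e-05), while rpl10a was at 1.19 ± 0.46 (adjusted p = 0.139). VEGF genes were higher in 9 of 13 cases (9), with flt1 at 4.49 ± 0.44, and venous and lymphatic genes in 10 of 13 (10 and 1), with gpr182 at 4.31 ± 0.35. These 3 lists held with an estimated correlation (adjusted p = 0.00217, 0.00217 and 0.00742). Myeloid genes were higher in 12 of 22 cases (15), with srgn at 5.09 ± 0.69, blood progenitor genes in 6 of 8 (6), with gfi1aa at 6.24 ± 1.01, and arterial genes in 4 of 9 (5), with sox17 at 6.34 ± 1.02 beside dll4, hey2 and dlc. Without AngioTag input 2 the progenitor count was 3. Lower were skeletal muscle genes in 11 of 29 cases (16), with actc1b at -2.21 ± 0.41. Part of this came from the inputs, since the muscle median was -1.08 in this contrast, -0.31 between the IP groups and 0.62 between the inputs. Also lower were pigment genes in 8 of 13 (11), with the TYRP1 copy ENSDARG00000029204 at -1.94 ± 0.36. Notochord genes were lower in 5 of 9 cases (6), with col9a2 at -2.20 ± 0.28 beside col8a1a, col9a1a, loxl5b and col11a2, and neural genes in 10 of 33 (14), with sox19a at -1.63 ± 0.29. The notochord count was 3 without AngioTag IP 3, and loxl5b had an adjusted p of 0.0754 with all 18 libraries in 1 fit. The neural count was 5 without AngioTag IP 3, AngioTag input 1 or 3 or RiboTag input 1, 6 without AngioTag input 2 or RiboTag input 2, and 16 (17) with same-numbered samples as a block. With an estimated correlation the camera calls of these last 7 lists were lost, at 0.0543 for myeloid, blood progenitor, arterial, pigment and notochord genes and 0.164 for muscle and neural genes.

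By this contrast 850 genes were higher and 672 lower of 19046 tested, against 1495 and 1484 with same-numbered samples as a block, 1379 and 1115 by DESeq2 and 306 lower with all 18 libraries in 1 fit. Counts of higher and lower genes were 560 and 273 without AngioTag IP 3, 557 and 297 without AngioTag input 1, and 553 and 306 without AngioTag input 3. The lower genes alone were 367 without AngioTag input 2 and 281, 332 and 327 without RiboTag inputs 1, 2 and 3. Mitochondrially encoded genes, which fell in both pull-downs, differed in 1 of 12 cases (2 adjusted over the list alone), mt-nd3 (1.73 ± 0.48), and not without AngioTag IP 2 or 3, any 1 AngioTag input, or RiboTag input 1 or 3 (adjusted p of 0.0706 to 0.108), with 2 called without RiboTag IP 2 or with the block and 3 without RiboTag IP 3.

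The difference between the AngioTag and FACS enrichments shows where the pull-down and the sorted cells part. Mitochondrially encoded genes had a lower enrichment in AngioTag in 11 of 12 cases (12 adjusted over the list alone), with mt-co1 at -4.04 ± 0.37 and a median of -3.80 (camera adjusted p = 1.68e-48, and 0.00799 with an estimated correlation). Skeletal muscle genes were higher in 17 of 29 cases (21), with the myosin genes myhz1.2 at 4.84 ± 0.58 and myhz2 at 3.69 ± 0.54, and neural genes in 14 of 33 (18), with ascl1b at 2.35 ± 0.48 and PAX6 (ENSDARG00000103379) at 2.22 ± 0.40. Camera found both lists up, at 1.51e-17 and 5.98e-10, but 0.372 for each with an estimated correlation. The muscle count was 11 without AngioTag IP 1, FACS sorted 3 or FACS total 1, 10 without AngioTag IP 2 or 3, 9 without AngioTag input 2, 7 without AngioTag input 3 or FACS sorted 1, and 4 without AngioTag input 1, and with same-numbered samples as a block it was 11 (26). The neural count was 7 without AngioTag IP 2, AngioTag input 2 or FACS total 1 or 2, 4 without AngioTag input 3 and 2 without AngioTag input 1. The cardiac myosin gene myh6 was higher (2.46 ± 0.34) as the only called cardiac gene of 10 (2 over the list alone), and without AngioTag IP 1 there were 2.

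Endothelial genes were lower in this contrast in 18 of 57 cases and higher in 1, nr2f2 (1.42 ± 0.35), with 25 and 1 adjusted over the list alone. The guidance receptor gene plxnd1 was at -4.48 ± 0.81, sox18 at -3.09 ± 0.52 and kdr at -2.56 ± 0.39, while kdrl was at -0.91 ± 0.36 (adjusted p = 0.13) and rpl10a at 1.00 ± 0.45 (adjusted p = 0.178). The number of lower genes was 8 without AngioTag input 1, 9 without AngioTag input 3 or FACS sorted 1 and 10 without FACS total 1. The call for nr2f2 was lost without AngioTag IP 2, any 1 AngioTag input, FACS sorted 1 or FACS total 1 or 2 (adjusted p of 0.0504 to 0.0802). The median was -1.04, and camera's adjusted p of 2.95e-10 was 0.372 with an estimated correlation. The ion channel gene piezo1 (-3.80 ± 0.51) was with klf2b and klf2a among 3 of 6 flow responsive genes lower (3 over the list alone), and 1 was lower without AngioTag input 1 or 3, FACS sorted 1 or FACS total 1 or 3. The call of klf2a was lost with same-numbered samples as a block (adjusted p = 0.0633), with all 18 libraries in 1 fit (0.0549), without a low-count filter (0.0502) and without 3 doubted libraries (0.0938). It was also lost without AngioTag IP 1 or 2, FACS sorted 1 or 2, any 1 AngioTag input or any 1 FACS total (0.0656 to 0.123). Of 10 blood progenitor genes gata2a (-2.19 ± 0.36) and myb were lower (2), and 1 was lower without AngioTag input 1 or 3 or FACS total 1. In all, 605 genes were higher and 1031 lower of 20153 tested, against 912 and 2145 by DESeq2 (median shift -0.163) and 409 and 1371 with median-of-ratios scaling (median shift -0.162). Both counts moved without AngioTag IP 3 (345 and 637), AngioTag input 1 (99 and 403), AngioTag input 3 (112 and 404), FACS sorted 1 (284 and 496) and FACS total 1 (296 and 489). The higher count moved without AngioTag IP 2 (401) and AngioTag input 2 (244).

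Across 17337 genes tested in both, the AngioTag and FACS enrichments had a Pearson correlation of 0.58 and a Spearman correlation of 0.52. In this set 1240 genes rose in both, where 294.0 would be given by independent calls, 861 fell in both (328.2), 16 rose in AngioTag and fell in FACS (334.9), and 65 did the opposite (288.1). For AngioTag and RiboTag over 17304 genes the correlations were 0.32 and 0.31, with 24 genes up in both (of 2055 up in AngioTag and 127 up in RiboTag), 1.59 times the number given by independent calls, 50 down in both (11.1), 0 up in AngioTag and down in RiboTag (10.7) and 7 the opposite (15.6). Neither pair shares libraries, genes are not independent replicates, and no p-value was computed for these 2 relations.

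AngioTag IP against RiboTag IP sets both pull-downs side by side. Endothelial genes were higher in the AngioTag IP in 47 of 56 cases and lower in 1 (50 and 2 adjusted over the list alone), with kdrl at 4.72 ± 0.40 and pecam1 at 5.72 ± 0.43. Myeloid genes were higher in 13 of 21 and lower in 1 (14 and 1), with lyz at 7.59 ± 0.60. The lower genes were ephb4a (-1.25), with an adjusted p of 0.0925 without AngioTag IP 3, and mmp9 (-2.43), with one of 0.0895 without RiboTag IP 1, and 2 endothelial genes were lower without RiboTag IP 3. Camera gave 1.51e-68 and 2.17e-15, but 0.146 and 0.278 with an estimated correlation. Cell cycle genes were lower in 11 of 28 cases (11), with mcm3 at -1.91 ± 0.29 and the cyclin gene ccna2 at -1.77 ± 0.35, in 6 without AngioTag IP 2 and in 4 without AngioTag IP 3. Pigment genes were lower in 9 of 13 cases (9), with foxd3 at -2.73 ± 0.33, and in 3 without AngioTag IP 3. Neural genes were lower in 14 of 32 (15), with sox19a at -1.75 ± 0.30, in 6 without AngioTag IP 1 or RiboTag IP 1 and in 2 without AngioTag IP 3. Camera gave these 3 lists 1.29e-05, 1.84e-05 and 2.52e-05, or 0.406, 0.293 and 0.427 with an estimated correlation. Skeletal muscle genes went both ways, with 4 of 29 higher and 10 lower (5 and 12) and a median of -0.31, and camera's 0.0448 was 0.647 with an estimated correlation. Those higher were 2, 1 and 0 without AngioTag IP 2, AngioTag IP 3 and RiboTag IP 1, and those lower were 4 without AngioTag IP 3. Cytosolic ribosomal protein genes, which held 20.3% ± 3.39 of AngioTag IP counts and 13.0% ± 5.04 of RiboTag IP counts, were higher in 8 of 81 cases (2), including rplp2 (2.54 ± 0.58) and rpl10a (1.75 ± 0.42, adjusted p = 0.014, and 0.0698 without AngioTag IP 3 and 0.0624 without RiboTag IP 1). That count was 5, 2 and 1 without AngioTag IP 1, 2 and 3, and 2 and 4 without RiboTag IP 1 and 3, and 14 with same-numbered samples as a block, and camera's 2.17e-06 was 0.647 with an estimated correlation. The median of this list was 0.72 here and 0.42 between the inputs of the same lines. In total 1685 genes were higher and 1498 lower of 17096. Upper-quartile scaling moved the median by -0.144 and gave 1419 and 1989, and all 18 libraries in 1 fit gave 3052 and 2973. With single libraries left out, 835 genes were lower without AngioTag IP 2, 806 and 370 passed without AngioTag IP 3, and 959 and 740 without RiboTag IP 1.

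The inputs of the lines served as background. Here kdrl was at 0.33 ± 0.14 (adjusted p = 0.2) and rpl10a at 0.54 ± 0.21 (adjusted p = 0.157), and edgeR called 0 of 54 endothelial genes (0 adjusted over the list alone), with 4 up and 9 down at an unadjusted p below 0.05 and 0 and 3 by DESeq2. The ferritin gene fthl28 (2.03 ± 0.17) was higher in AngioTag input and eef2a.1 (-2.08 ± 0.24) and PLPPR3 (-1.81 ± 0.18) lower, calls that ended with all 18 libraries in 1 fit (adjusted p of 0.0929, 0.316 and 0.57). Skeletal muscle genes were higher in 5 of 29 cases (19 up and 1 down over the list alone). They included the parvalbumin gene pvalb1 (1.72) with pvalb2, 2 TNNT3 copies and myl1. Lens genes were higher in 4 of 14 cases (12 and 1), including crybb1 (1.07) with MIP, CRYBA2 and cryba4. The call of pvalb1 ended with same-numbered samples as a block (adjusted p = 0.0671), and with all 18 libraries in 1 fit those of crybb1 (0.316), CRYBA2 (0.506), MIP (0.534), cryba4 (0.558), pvalb1 (0.569), pvalb2 (0.57) and the TNNT3 copies (0.595 and 0.617) did. The muscle count was 12 without AngioTag input 1, 0 without AngioTag input 2 or 3 or RiboTag input 1, 3 without RiboTag input 2 and 18 by DESeq2. The lens count was 10 without AngioTag input 1, 1 without AngioTag input 2, 0 without AngioTag input 3 or RiboTag input 1, 11 by DESeq2 and 7 with the block. Camera's 3.06e-11 and 4.58e-11 were 0.862 each with an estimated correlation. Cytosolic ribosomal protein genes had a median of 0.42 and a camera adjusted p of 9.31e-15, or 0.879 with an estimated correlation. By edgeR 0 of 81 passed (0 adjusted over the list alone), with 30 up and 0 down at an unadjusted p below 0.05 and 10 and 0 by DESeq2. In all, 151 genes were higher and 156 lower of 18458, with 753 and 841 by DESeq2, 282 and 280 without a low-count filter and 1 and 5 with all 18 libraries in 1 fit. These counts became 420 and 282, 20 and 39, and 8 and 12 without AngioTag inputs 1, 2 and 3, and 3 and 12, 98 and 102, and 251 and 443 without RiboTag inputs 1, 2 and 3.

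FACS total against AngioTag input compares the whole-embryo references of the AngioTag line. Immediate early and stress genes were higher in FACS total in 37 of 37 cases (37 adjusted over the list alone), with a median of 3.46. The transcription factor gene fosab was at 823 ± 394 CPM in FACS total and 3.54 ± 1.11 in AngioTag input (7.74 ± 0.53, adjusted p = 5.13e-05), and fosl1a at 8.11 ± 0.61. Heat shock genes were higher in 6 of 14 cases and lower in 1 (6 and 1), with hsp70l at 4.53 ± 0.65, bag3 at 2.29 ± 0.18 and hspb8 at -1.31 ± 0.26, and 5 were lower without FACS total 3. Yolk and liver genes were lower in 14 of 15 cases (14), with apobb.1 at 2.07 ± 1.03 against 830.4 ± 153 CPM (-8.75 ± 0.51) and apoa1b at -7.98 ± 0.53. Skeletal muscle genes were lower in 24 of 29 cases and higher in 1 (24 and 1), with actc1b at -2.88 ± 0.43, and 15 were lower without FACS total 1. The rise in myf5 (0.90) was lost without AngioTag input 2 or 3. Cardiac genes were lower in 5 of 9 (6), with myl7 at -3.41 ± 0.27 beside cmlc1, hand2, myh6 and nppa. Mitochondrial ribosomal protein genes were lower in 51 of 73 (53), with mrps7 at -1.57 ± 0.22, in 32 without AngioTag input 2 and in 30 without FACS total 1. Camera adjusted p-values were 5.14e-34, 2.04e-27, 3.88e-07, 0.000668 and 1.8e-09 for the immediate early, yolk, muscle, cardiac and mitochondrial ribosomal lists, and 0.3, 0.3, 0.69, 0.441 and 0.69 with an estimated correlation. The heat shock list had 0.349. Endothelial genes were higher in 20 of 55 cases and lower in 6 (20 and 6), with rasgrp3 at 6.94 ± 0.49 and erg at -0.97, and arterial genes in 6 of 8 and 1 (6 and 1), with notch3 at 3.61 ± 0.49. Their medians were 0.07 and 1.25 and their camera p-values 0.125 and 0.0403, or 0.69 each with an estimated correlation. The lower endothelial genes were 22 without FACS total 3, 3 without FACS total 2 or AngioTag input 1 and 2 without AngioTag input 2 or 3. The lower arterial gene, hey2, was lost without FACS total 2 or any 1 input, with the block and with all 18 libraries in 1 fit (adjusted p of 0.0557 to 0.117). The references of the AngioTag minus FACS contrast thus differed in single endothelial genes, at a share near the 46.3% called over all genes. A difference of the list as a whole was not shown. Levels of kdrl (0.17 ± 0.19, adjusted p = 0.499) and rpl10a (-0.43 ± 0.38, adjusted p = 0.371) did not pass. In total 4848 genes were higher and 4075 lower of 19266, with 2488 lower when all 18 libraries shared 1 fit (median shift 0.106). Left out singly, FACS total 1, AngioTag input 2 and AngioTag input 3 gave 2695, 2372 and 2499 lower.

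**Figure D3:**
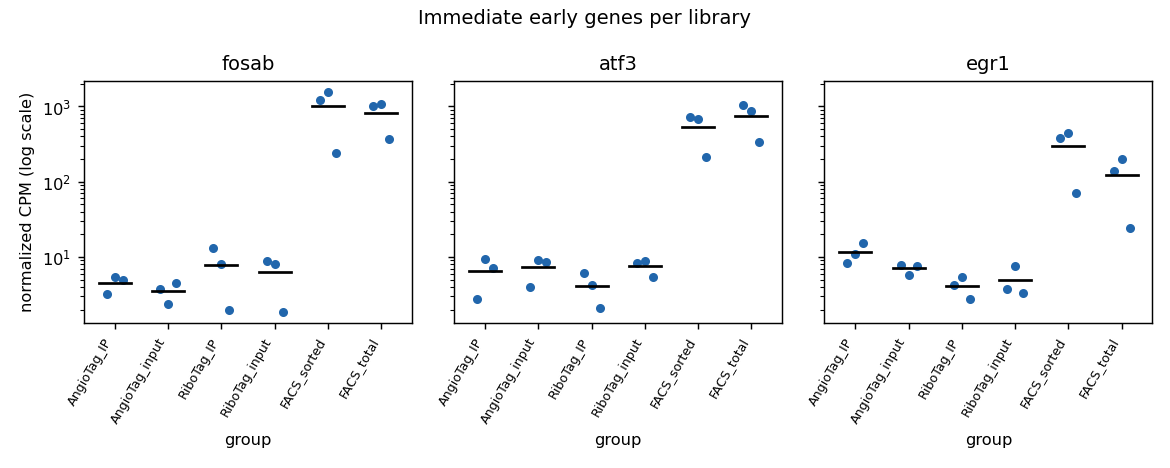
Levels of the immediate early genes fosab, atf3 and egr1 (y axis, normalized CPM on a log scale) in the 6 groups (x axis), with a point per library and a line at each group's mean. For fosab the FACS libraries lie between 238.9 and 1554 CPM and the IP and input libraries between 1.855 and 13.21.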

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

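The tests of carried-over RNA, of RiboTag IP 2, of depth, of a shared preparation, of handling and of RNA selection, and the regrouping of libraries, were chosen after the result was seen. The contrasts, the block, the scalings and the libraries left out that they draw on were planned, and the bounds for the scalings and for thinned libraries were written before these were run. Enrichments that differed between systems by an interaction test were picked out in this first paragraph, and the 3 patterns after it were taken up for their values in the comparisons. The AngioTag minus RiboTag contrast gave 850 genes higher and 672 lower, with median differences of 3.86 for endothelial, 3.13 for venous and lymphatic and 1.42 for VEGF genes. Its largest differences upward under the naming rule were F2RL2 (8.58), pdia2 (7.65), gfi1aa (6.24), pecam1b (6.17), lyz (6.1), spi2 (6.08), actc1c (6.05) and GJA5 (5.64), with clec14a (5.39) and pecam1 (5.33) behind them. Its largest downward were col8a1a (-3.85), RASSF8 (-3.35), acsl2 (-3.11), angptl2a (-3.07), col5a3b (-2.98) and CSRNP1 (-2.97). The AngioTag minus FACS contrast gave 605 genes higher and 1031 lower, with a median of -3.80 for mitochondrially encoded genes. Upward were actc1c (8.27), hip1ra (7.64), FBXO40 (5.79), tipin (5.59), myhz1.2 (4.84), myhz1.1 (4.62), cyt1 (4.33), myhz1.3 (4.24), ngs (3.96) and myh14 (3.81), and downward SKIL (-7.60), MBNL1 (-6.92), ITPR2 (-6.17), ARHGEF3 (-6.08), mt-nd4l (-6.02) and FOXF1 (-5.97). The AngioTag IP mean of hip1ra, 889.7 ± 1082 CPM, rests on 1 library, SKIL and MBNL1 had few or no counts in the AngioTag IP, and the actin and myosin copies can share reads with near-identical paralogs. With same-numbered samples as a block, the calls of SKIL (adjusted p = 0.0594), cyt1 (0.0612), ngs (0.0699) and tipin (0.0753) in the AngioTag minus FACS contrast were lost, and the call of acsl2 in the other was lost under 5 settings (0.0512 to 0.0587). With any 1 of the libraries left out, except AngioTag IP 1 and RiboTag IP 3, acsl2 lost its call (0.0679 to 0.147). Others that lost theirs without single libraries were CSRNP1 (0.0573 to 0.112), SKIL (0.0536 and 0.0597), tipin (0.0539 to 0.0627), cyt1 (0.0577 and 0.0599) and ngs (0.0511 to 0.0757).

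Neural and skeletal muscle genes fell less in the AngioTag IP than in sorted cells. Over all members tested the AngioTag and FACS medians were -0.97 and -3.26 for muscle and -0.70 and -2.13 for neural genes, and for the 56 called lower in sorted cells, a choice that favours the pattern, -0.87 and -2.46. Each fall is against its own reference, and the references differed in these lists. With the block, FACS total lay below AngioTag input in 25 of 29 muscle genes and above it in 1 (median -2.41). For neural genes these were 14 and 4 of 33 (-0.55). A lower FACS total makes a fall in sorted cells smaller. Whole-embryo RNA carried through the immunoprecipitation could not be told apart from expression of the tag in other cells, since no IP without the tag was made and the 18 members at least 8-fold lower in sorted cells had an interquartile range of 0.86. Of the 62 members tested 5 were called above their own input, while 12.1% of all genes tested rose. Among the 5 were myhz1.1 (1.33 ± 0.32), myhz1.2 (1.27 ± 0.30) and myhz1.3 (1.07 ± 0.20), copies that can share reads. RNA carried over at its input level would put no gene above input, but these copies were picked for lying above it. Such RNA as the whole cause was therefore left open for them. Under 12 alternatives on the same libraries the copies stayed at 0.87 to 1.57, 2.77 to 8.71 standard errors above input. Only myhz1.3 kept its call without AngioTag IP 3. With all 18 libraries in 1 fit only myhz1.2 did, and the other 2 called, smyhc1 (1.93 standard errors) and isl1 (2.33), were left open too. Carry-over of RNA that any pull-down enriches was not tested. With the block 0 of 29 muscle genes were higher in AngioTag minus RiboTag. Under the less favourable of 2 other scalings 25 of 31 calls were left. Median-of-ratios and upper-quartile scaling moved the genes by a median of only -0.162 and 0.017. Shifts this small beside the gap between the AngioTag and FACS medians could hardly end most calls, so the count does not decide on normalization. A larger shift shared by all genes was not tested.

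Few genes passed in RiboTag IP against input. A shared preparation of same-numbered samples fitted this, since 2574 genes passed with these samples as a block and 217 without it. A block takes up anything that same-numbered samples share, so the rise in calls does not single out a preparation. Without a block DESeq2 called 800 genes higher and 649 lower, and all 18 libraries in 1 fit gave 374 and 439. The low count thus also depended on the test and the fit. Whether RiboTag IP 2 alone widened the spread could not be told apart, since 1878 genes passed without it but 622 without IP 3 and 5 without IP 1. Lower depth was excluded as the whole cause: with every AngioTag library above the lowest RiboTag total, 29.5 M counts, thinned to it, at least 4158 genes passed in AngioTag (4300 without thinning), and at least 6194 without AngioTag IP 1, the single AngioTag library below that total (20.7 M). No biological explanation was tested.

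Immediate early genes were higher in FACS total than in AngioTag input. Handling of the cells before RNA was taken could not be told apart from other causes shared by FACS sorted and FACS total. All 37 members called (100%) also had a FACS sorted mean above all 12 IP and input libraries, as any such cause predicts. Collection and handling are also confounded here. With same-numbered samples as a block, yolk and liver genes were lower in FACS total in 14 of 15 cases (median -7.46). The 2 references thus differed in other genes as well, and what lowered the yolk genes was not tested. Under the less favourable of 2 other scalings 37 calls were left. Median-of-ratios and upper-quartile scaling moved the genes by a median of only 0.028 and 0.046 on the log2 scale. Shifts this small could hardly end a call, so the count does not decide on normalization. Another RNA selection could not be told apart, with a histone median of -0.49 between the bounds. A library batch was not tested, since the histone median does not bear on it. No biological explanation was tested.

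Libraries were also regrouped in other splits of the same sizes. For the 6 comparisons of 2 groups, 1 of 10 splits, the real one, called as many genes as itself (4300 for AngioTag IP against input, 217 for RiboTag, 5546 for FACS, 3183 for AngioTag IP against RiboTag IP, 307 for the inputs and 8923 for FACS total against AngioTag input), and the others called 0 at most, so the share could not fall under 1 in 10. For the AngioTag minus RiboTag contrast 9 of 100 splits called at least the real 1522, up to 4820, which points to a structure of the samples. All 8 others as large were among the 9 that kept the IP libraries in their lines and so still held the difference between the IP groups, and the 90 with them mixed called 0 at most. This count therefore neither excluded chance nor spoke for it. For the AngioTag minus FACS contrast 4 of 100 splits called at least the real 1636, up to 9027, with the 3 others as large among the 8 that kept the IP and sorted side and 8 genes at most in the 91 with it mixed, and this count is limited in the same way.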

How the results depend on the processing

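No named gene changed sign, and the alternatives that left out zgc:158463 or 3 doubted libraries, or took another reference for sorted cells, were chosen after seeing the data. Of 6841 checks of 653 named results under other settings, 6544 kept their side of the threshold and 297 lost it, and of 4746 with 1 library left out, 3830 kept it and 916 lost it. The cause was not tested for any change here, apart from those that follow from fewer libraries or a stricter threshold. The larger side of the counts did turn in places: with upper-quartile scaling AngioTag minus RiboTag gave 779 higher and 870 lower and RiboTag 88 and 92, and FACS gave 2930 and 2562 with median-of-ratios scaling and 3395 and 3143 by DESeq2. AngioTag IP against input (2170 and 2130) turned to 1461 and 3078 with upper-quartile scaling, 2352 and 2552 with the block and 2733 and 2878 by DESeq2. It also turned with all 18 libraries in 1 fit (1553 and 1573) and the stricter filter (2026 and 2078). AngioTag IP against RiboTag IP turned with upper-quartile scaling (1419 and 1989), RiboTag with all 18 libraries in 1 fit (374 and 439) and the inputs with the block (112 and 68). Values below are genes higher and lower, beside those in the report. With an absolute log2 fold change of at least 1, AngioTag IP against input gave 1268 and 1608, so the larger side turned there too. The inputs then gave 96 and 141, and FACS total against AngioTag input 3985 and 2519. With all 18 libraries in 1 fit, RiboTag gave 374 and 439, the AngioTag minus RiboTag contrast 306 lower, AngioTag IP against RiboTag IP 3052 and 2973, the inputs 1 and 5, and FACS total against AngioTag input 2488 lower (4200 higher, a share of 62.8% against 54.3%). With same-numbered samples as a block, RiboTag gave 1306 and 1268, the AngioTag minus RiboTag contrast 1495 and 1484, and the inputs 68 lower, and 43 of the 653 named results lost their call. DESeq2 gave 800 and 649 for RiboTag, 1379 and 1115 for AngioTag minus RiboTag, 912 and 2145 for AngioTag minus FACS, and 753 and 841 for the inputs. No low-count filter gave 282 and 280 for the inputs. Without the doubted libraries, AngioTag minus RiboTag gave 1739 and 1368, AngioTag minus FACS 918 higher and AngioTag IP against RiboTag IP 2794 higher. With AngioTag input as the reference for sorted cells, 6075 and 6041 passed. For genes with an average of at least 10 CPM, AngioTag enrichment and FACS enrichment across genes correlated at 0.736. AngioTag enrichment and RiboTag enrichment across genes then correlated at 0.209.

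With each library left out in turn, counts higher and lower ranged from 1026 to 3099 and 695 to 3424 for AngioTag, 0 to 864 and 5 to 1014 for RiboTag, 1668 to 3108 and 1563 to 2741 for FACS, 553 to 1181 and 273 to 946 for AngioTag minus RiboTag, 99 to 736 and 403 to 1251 for AngioTag minus FACS, 806 to 1764 and 370 to 1382 for AngioTag IP against RiboTag IP, 3 to 420 and 12 to 443 for the inputs, and 3518 to 6367 and 2372 to 6002 for FACS total against AngioTag input. The correlations ranged from 0.526 to 0.609 for AngioTag and FACS and from 0.184 to 0.337 for AngioTag and RiboTag. The camera calls that the block or median-of-ratios scaling changed and that are not in the report were, with the block, erythroid (0.0201) and heat shock (0.0383) gained in AngioTag, cytosolic ribosomal proteins (0.00363) gained in RiboTag, yolk (0.049) gained in FACS, pronephros (0.0184) gained in AngioTag minus FACS, and mitochondrial ribosomal proteins (0.0201) gained and skeletal muscle (0.0856) lost in AngioTag IP against RiboTag IP. With that scaling, Notch (0.0445) was gained in AngioTag minus RiboTag and VEGF (0.0473) in AngioTag minus FACS, and skeletal muscle (0.0506) was lost in AngioTag IP against RiboTag IP.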

Other observations

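The hypothesis below was tested with a list set after the result was seen in RiboTag, and its prediction was written before the AngioTag values of the list were computed. Genes of the basement membrane went both ways in sorted cells against FACS total, with 9 of 21 up and 5 down (9 and 6 adjusted over the list alone), a median of -0.22 and a mean of 0.65. The collagen genes col4a1 (3.27 ± 0.32) and col4a2 (3.28 ± 0.39) and mmrn2a (4.44 ± 0.37) were up and lamb2 (-1.91 ± 0.30), NID1 (ENSDARG00000068710), col4a5, col4a6 and FN1 were down, the last 3 named after their values were seen. The falls were 2 without FACS sorted 1 or FACS total 1 and 3 without FACS sorted 3 or FACS total 2, and camera's adjusted p of 0.03 was 0.309 with an estimated correlation. Notch genes rose in 6 of 19 cases and fell in 2 (6 and 2 adjusted over the list alone), with the target gene hey2 at 3.73 ± 0.29 and the ligand genes dlc at 2.64 ± 0.36 and dlb at -2.01 ± 0.34, which fell with jag1a. They rose in 3 without FACS sorted 1 or any FACS total, and 1 fell without FACS sorted 1 or 3 or FACS total 1 or 2 (camera adjusted p = 0.0191, and 0.648 with an estimated correlation).

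In FACS total against AngioTag input, the myeloid list had a median of -0.11 and a mean of 0.98, with 6 of 22 higher (6 adjusted over the list alone), among them the protease genes mmp9 (6.04 ± 0.32) and mmp13a (4.81 ± 0.36) and the cytokine gene il1b (3.94 ± 0.31). Lower were cyba (-1.32) and arpc1b (-0.85) (2 over the list alone), 0 without AngioTag input 2 or 3 or FACS total 1 and 1 without FACS total 2, and arpc1b had an adjusted p of 0.0575 with all 18 libraries in 1 fit. Camera gave 0.043, or 0.69 with an estimated correlation. Replication and mitosis genes had a lower enrichment in AngioTag than in RiboTag in 6 of 28 cases (8 over the list alone), with mcm3 at -1.49 ± 0.28 and mcm7 at -1.47 ± 0.28, and in 3 without AngioTag IP 3, AngioTag input 1 or RiboTag input 1 (camera adjusted p = 0.000113, and 0.262 with an estimated correlation).

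One hypothesis was that splicing factor messages are over-represented in ribosome pull-downs, after genes such as srsf3a, wbp11, hnrnpa1a, acin1a and ewsr1b were noticed in RiboTag. With the genes noticed left out, 10 of 128 splicing factor genes rose and 4 fell in AngioTag IP against input, with a median of 0.26 and a camera p of 0.0244, which met the prediction as it was written. The shares up and down, 7.81% and 3.12%, were below the 12.1% and 11.9% of all genes tested, so the count itself shows no excess. It was 0 without IP 3 or any 1 input and 37 without IP 2. The camera p was 0.56 with an estimated correlation, and 0 and 0 passed adjusted over the list alone. The AngioTag level of acin1a had been seen before. In RiboTag 10 of 129 rose and 0 fell (7.75% and 0% against 0.7% and 0.496% of all genes), 70 and 1 adjusted over the list alone, with a median of 0.66 and a camera p of 2.72e-24 (0.00169 with an estimated correlation). The RiboTag rises were 0 without IP 1 or any 1 input, 51 and 31 without IP 2 and 3, and 69 with same-numbered samples as a block. Adjusted over the list alone they were 42, 74 and 65 without IP 1, 2 and 3. They were 6, 7 and 37 without inputs 1, 2 and 3, and 79 with the block. In FACS 3 of 128 rose and 4 fell (0 and 0 adjusted over the list alone), with a median of -0.19, a camera p of 0.218, and 0.522 with an estimated correlation.

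The gene zgc:158463 had a log2 fold change of 8.63 in sorted cells (adjusted p = 0.0182) and of 4.46 in the AngioTag IP (adjusted p = 0.0935), values carried by 1 library each. Its levels in FACS sorted 1 to 3 were 205.7, 179000 and 2672 CPM, and those in AngioTag IP 1 to 3 were 49820, 181.6 and 1361.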
